A study of Sus scrofa with 5 samples.

How the data were processed

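Single-cell RNA was measured in 5 libraries of pig skin, 1 library per group. Full-thickness wounds on pigs were covered with split-thickness skin grafts, either untreated or under a hydrogel carrying an inhibitor of focal adhesion kinase (FAK, the product of PTK2). Grafts were collected at day 7 or day 90, and unwounded skin served as the reference. Tissue was dissociated with enzymes and cells were captured with 10x Genomics chemistry. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, produced by the authors with Cell Ranger, per the labels. Each value was a whole number. The version of Cell Ranger and the genome build were not given in the sources used here. The matrix headers carry software version 3.1.0 without saying what it refers to, and the submitters name Seurat 3.1.1 for steps after the counts, which were not used here. How many animals stand behind each library was not stated, although the series describes multiple pigs.

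The deposited matrices held 32554 barcodes in total, 9544 in the untreated graft at day 7, 10962 in the inhibitor graft at day 7, 6074 and 4091 in the corresponding grafts at day 90, and 1883 in unwounded skin. The fewest UMIs in any barcode of a library lay between 500 and 503. Of 20286 gene identifiers, 15344 had a symbol, 670 of them from a symbol table of the pig assembly Sscrofa11.1, and the others were left out of lists and named genes. Cells were kept with at least 500 genes and at most 25% of UMIs from 13 mitochondrially encoded genes. Doublets were scored per library with Scrublet as provided in Scanpy. Its automatic threshold called 0, 0, 96, 12 and 3 cells in the order of libraries above, so the top-scoring cells were removed at an expected rate of 0.8% per 1000 cells, which gave 524, 700, 255, 116 and 19 cells. This left 26842 cells, with median UMIs per cell of 6328.5, 5474, 9579, 8023 and 7462.

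All libraries were clustered together without batch integration, because each library is its own group. The steps were 2000 highly variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1, which gave 33 clusters. A cluster took the name of a cell class by fixed marker lists (16 classes, 134 of 147 marker genes measured). A name needed a marker score of at least 0.8, at least 3 markers and no fewer than 50% of those measured raised 1.5-fold, and a lead of 0.5 over the next class. It was withheld where the top 10 genes of the cluster held more markers of another class than of its own, or none of its own in a cluster of low UMI counts. Clusters that failed the rule (5) stayed unnamed. Classes are called fibroblast-like and so on, because they rest on RNA markers alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and Matplotlib 3.10.9 were used.

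UMIs were summed over the cells of a class in a library and scaled to CPM, counts per 1000000 UMIs of that sum. Ratios between libraries are given as folds or on the log2 scale, with exact conditional binomial intervals, and CPM values have exact Poisson intervals. Shares of cells have exact Clopper-Pearson intervals, and for a share of 0 the upper limit is given beside the share that 3 cells would make. All intervals are at 95%. With 1 library per group there was no spread between replicates, no p-value could be computed, and the intervals cover counting error only. A gene counted as higher or lower when its ratio reached 1.5-fold, which is a rule of size and not a test. A ratio against 0 UMIs was computed against a floor of 3 counts in the class sum.

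Lists of genes (22 lists, 315 of 357 genes measured) were fixed before the data were examined, together with the markers, the comparisons, the naming of genes and 12 alternative settings. The lists were collagens, wound matrix and crosslinking, unwounded-dermis fibroblast genes, contractile genes, focal adhesion, YAP/TAZ targets, TGF-beta response, PI3K-AKT, matrix proteases and inhibitors, interferon response, chemokines and inflammatory cytokines, tissue-macrophage genes, lipid-handling macrophage genes, antigen presentation, wound keratinocyte, differentiated keratinocyte, angiogenic endothelial, endothelial activation, immediate early, heat shock, cell cycle, and hypoxia and glycolysis. The immediate early and heat shock genes are also raised by enzymatic digestion. The plan also set the class for most lists. Matrix, contractile, focal adhesion, YAP/TAZ, TGF-beta, PI3K-AKT and protease lists were meant for fibroblast-like cells. Interferon, chemokine, macrophage and antigen presentation lists were meant for myeloid-like cells. Medians of these lists in other groups of cells lie beyond the plan. Except for the interferon response by class, they were not computed under the alternative settings. A list's value is the median log2 ratio of its members at 50 CPM or more in either library. It was set against 10000 random lists of genes of like expression, and the percentile among them is a description. Its counting interval came from 1000 Poisson resamples. A median at or below percentile 2.5, or at or above 97.5, is called outside the random lists. Genes of the lists without a matching symbol were left out and count as not measured, among them JUN, IL1B, S100A9, MMP1, KRT6A, SLA-DRA and IFIT3. Some may be counted under another symbol, since HLA-DRA, the human name for SLA-DRA, is a leading gene of unnamed cluster 20.

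Named genes are the 10 with the largest and the 10 with the smallest ratio between treated and untreated grafts at each day in fibroblast-like and in myeloid-like cells, and 5 each way in the comparisons with unwounded skin and between days. They needed a symbol, 100 CPM in 1 of the 2 libraries and 50 UMIs in the sums together. Mitochondrial, ribosomal protein, haemoglobin and XIST genes were excluded. To keep out free RNA, the higher value also had to be at least 50% of the highest CPM of any other compared class in that library. Up to 2 members each way per list followed, and 6 genes were always named (PTK2, ACTA2, COL1A1, COL3A1, EGR1, CXCL10).

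The comparisons were the inhibitor graft against the untreated graft at each day, each graft against unwounded skin, and day 90 against day 7. A class was compared where both libraries held at least 100 cells. The exception was myeloid-like cells at day 90, compared on 50 against 261 cells. The alternative settings fixed in advance were looser and stricter cell filters, doublets kept, Leiden resolution 0.5 and 2, each library clustered alone, each cell assigned by its own markers, median-ratio scaling, CPM without the 50 most abundant genes, the mean of per-cell CPM, and list members at 10 CPM or at 1 UMI. Another 2 were chosen after seeing the data. In the first, the 3 fibroblast-like clusters with at least 100 cells in both libraries of a treatment comparison weighed the same. In the second, an unnamed cluster led by SPP1 and ARG1 (cluster 14) was counted as myeloid-like. Intervals, list medians and the size rule were tested on simulated data made from the depth of real clusters. In the smallest and the largest cluster tested, 100 of 100 genes changed by 2-fold to 4-fold passed the size rule, none of the 50 genes changed by 1.25-fold did, and the intervals held the true ratio for 95.5% and 95.0% of genes. Genes changed by amounts next to the 1.5-fold rule are not in these counts. The simulated counts had Poisson error alone and covered genes at 100 CPM or more. This checks the arithmetic, and cannot show how the rules hold under variation between cells or animals.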

Results

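RNA of single cells was compared between 5 pig skin libraries, namely untreated split-thickness grafts and grafts treated with the FAK inhibitor hydrogel, each at day 7 and day 90, and unwounded skin. Each group is 1 library, so no value could be checked against a replicate and no p-value is given. The number of animals behind a library was not stated. The libraries held 74694696 UMIs in the untreated graft and 79671374 in the inhibitor graft at day 7, 79530631 and 50384513 at day 90, and 18485301 in unwounded skin. After filtering, 7566, 8653, 5388, 3693 and 1542 cells remained in that order. Mitochondrial genes took a median of 4.64% and 2.96% of UMIs per cell at day 7, 2.93% and 4.23% at day 90, and 4.82% in unwounded skin, so the treated library was the lower one at day 7 and the higher one at day 90.

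The first question was which kinds of cells each graft yielded. At day 90, fibroblast-like cells made up 39.0% of cells in the untreated graft (95% interval 37.7 to 40.3) and 21.4% with the inhibitor (20.1 to 22.7), near the 17.2% of unwounded skin (15.3 to 19.2). Endothelial-like cells went the other way at day 90, 23.9% against 36.5%, with 42.1% in unwounded skin, and so did pericyte or smooth muscle-like cells, 18.4% against 28.2%, with 20.0% in unwounded skin, which was nearer the untreated graft. With each library clustered alone, the endothelial-like shares at day 90 were 23.9% and 27.5%, with 35.1% in unwounded skin. At day 7 the T or NK-like cells were 12.7% of the untreated and 21.9% of the treated graft, a ratio of 1.73, and 1.49% of unwounded skin. Myeloid-like cells made up 3.95% and 1.62% at day 7, a ratio of 0.41. That ratio moved to 0.84 when each library was clustered alone and to 0.79 when cluster 14, an unnamed cluster led by SPP1 and ARG1, was counted with them. Cluster 14 itself took 4.73% and 5.27% of cells at day 7. Its best class by marker score was myeloid, with 13 of 14 markers raised. The name was withheld because its top 10 genes held 2 markers of another class and 0 of its own. Myeloid-like cells were thus those of cluster 16 alone, led by C1QB, C4BPA and C1QC. At day 90 myeloid-like cells were 4.84% of the untreated and 1.35% of the treated graft.

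Keratinocyte-like cells made up 6.12% and 4.13% of the untreated and treated graft at day 7, under 2% of either graft at day 90 (0.594% and 1.68%), and 8.89% of unwounded skin. Mast-like cells ranged from 3.83% in unwounded skin to 5.53% in the untreated graft at day 7. With the stricter cell filter that range was 1.38% (untreated graft at day 90) to 5.66%, and T or NK-like cells at day 7 fell to 6.68% and 9.09%. B or plasma-like cells were 0.714%, 0.786% and 1.10% of the untreated graft at day 7, the treated graft at day 7 and the untreated graft at day 90. None was found among 3693 cells of the treated graft at day 90, which allows a share of up to 0.0812% with 3 cells as the limit, nor among 1542 cells of unwounded skin, which allows 0.195%. Digestion and capture also set these shares.

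**Figure D1:**
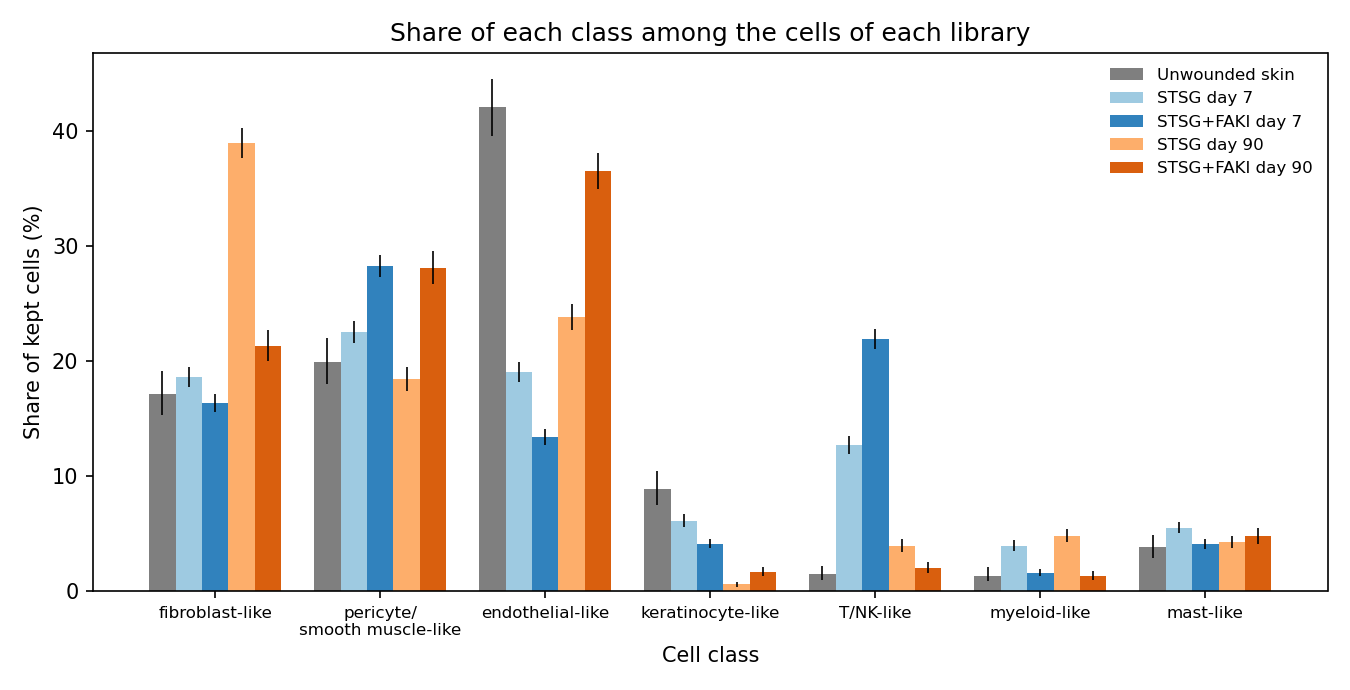
Share of kept cells (percent, vertical axis) taken by each cell class in the 5 libraries, with 95% Clopper-Pearson intervals that cover counting error only. Fibroblast-like cells take 39.0% of the untreated graft at day 90 and 21.4% of the treated one.

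The next question was how fibroblast-like RNA differed between the treated and the untreated graft at day 7, where 1408 untreated and 1419 treated cells were compared. Interferon response genes were higher with the inhibitor, genes of unwounded dermal fibroblasts were lower, and collagens were slightly lower. The list of interferon response genes had a median of 1.11 on the log2 scale (interval 1.07 to 1.18), with 9 of 10 genes higher, 0 lower and 1 in between, above all random lists. IFI6 rose 2.04-fold (2014 against 988.9 CPM), the transcription factor IRF1 2.44-fold, and the immunoproteasome gene PSMB9 3.55-fold. Antigen presentation genes had a median of 1.20, with 3 of 5 higher. Only 9 of the 15 genes on that list had a matching symbol, and SLA-1, SLA-2 and SLA-3 were not among them. On the log2 scale PSMB9 (1.83) and PSMB8 (1.31) were higher, while B2M (0.39) and CD74 (-0.05) stayed below the 1.5-fold rule. CXCL10, a chemokine that draws T cells, stood at 624.6 against 20.2 CPM, 30.9-fold higher (27.8 to 34.4). Its level was 8094 CPM in pericyte or smooth muscle-like cells of the same library, so free RNA from other cells remained possible. On the log2 scale its ratio of 4.95 became 5.78 with the looser cell filter and 4.36 with the mean of per-cell CPM.

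The unwounded-dermis list lay at -0.55 (-0.59 to -0.49), with 0 of 15 genes higher, 7 lower and 8 in between. PI16, a marker of adventitial fibroblasts, was 2.40-fold lower, the matrix glycoprotein TNXB 2.44-fold lower, and IGFBP5, which binds insulin-like growth factors, 2.94-fold lower. Collagens lay at -0.32 (-0.34 to -0.30), below all random lists. Of 14 genes, 2 were lower, COL14A1 (1.86-fold) and COL8A1 (1.55-fold), and 12 were in between, such as COL1A1 with 27430 against 33900 CPM (ratio 0.809) and COL3A1 (ratio 0.750). Wound matrix and crosslinking genes lay at -0.16, with 2 of 18 lower, the periostin gene POSTN (4328 against 7284 CPM) and the proteoglycan VCAN (2.02-fold), and 16 in between, such as TNC at 1.27. YAP/TAZ targets, which respond to mechanical tension, lay at -0.22 at percentile 0.7, with 2 of 12 lower, CCN2 (ratio 0.501) and CCDC80 (1.89-fold).

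Contractile genes at day 7 had a median of 0.21 (2 of 9 higher, TPM2 1.76-fold and TPM1 1.74-fold), with ACTA2, the smooth muscle actin of myofibroblasts, at 0.967. Focal adhesion genes lay at -0.05 with 0 of 15 changed, TGF-beta response genes at -0.11 (1 of 10 higher, the activin subunit INHBA, and 1 lower), and the PI3K-AKT list at -0.35 on 2 genes (percentile 2.02, outside the random lists). PTK2, which encodes FAK itself, had 22.0 against 27.4 CPM (ratio 0.802, 0.704 to 0.915). Chemokines and inflammatory cytokines lay at 0.22 (3 of 14 higher, 1 lower). The lists also raised by digestion were 0.23 for immediate early genes (3 of 12 higher, among them EGR1 1.59-fold, and KLF2 lower) and 0.21 for heat shock genes (1 of 10 higher, the co-chaperone DNAJB1 at 2.39-fold). Hypoxia and glycolysis genes lay at 0.38, percentile 99.6, with 1 of 7 higher (ADM, the vasodilator adrenomedullin, 2.32-fold), but at -0.02 with members at 1 UMI. Matrix proteases and inhibitors lay at -0.13, also below the random lists, with 2 of 11 higher, including the stromelysin MMP3 at 3.43-fold, and at 0.26 with members at 10 CPM. The cell cycle list held 1 gene at this level, with a log2 ratio of 0.54.

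Among the 20 genes with the largest ratios, the highest were SERPINE2, a serine protease inhibitor (262.9 against 27.94 CPM, 9.41-fold, 8.59 to 10.3), HPS5 (2464 against 299.6 CPM, 8.23-fold) and the cytokine IL11 (374.2 against 60.66 CPM, 6.17-fold). ODAPH followed at 2.11-fold. These 4 are leading genes of fibroblast-like cluster 9, which took 22.4% of untreated and 33.3% of treated fibroblast-like cells. HPS5 lies near SAA2 and SAA4 in a gene table of assembly Sscrofa11.1, and the annotation used for counting was not given, so the origin of its UMIs is uncertain. Outside that group, the signalling ligand WNT5A rose 2.30-fold and the GTPase gene RRAD 2.01-fold. The lowest were HAS1, a hyaluronan synthase (24.95 against 108.4 CPM, 4.34-fold lower), the complement gene C4A (2.73-fold) and the Wnt modulator SFRP4 (2.16-fold), the latter pair leading genes of cluster 7, and the chemokine CXCL12 (2.03-fold), the axon guidance gene SLIT2 (2.04-fold) and the co-receptor TGFBR3 (2.03-fold). All 20 kept their direction and passed 1.5-fold when the 3 shared fibroblast-like clusters weighed the same, a setting chosen after seeing the data.

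**Figure D2:**
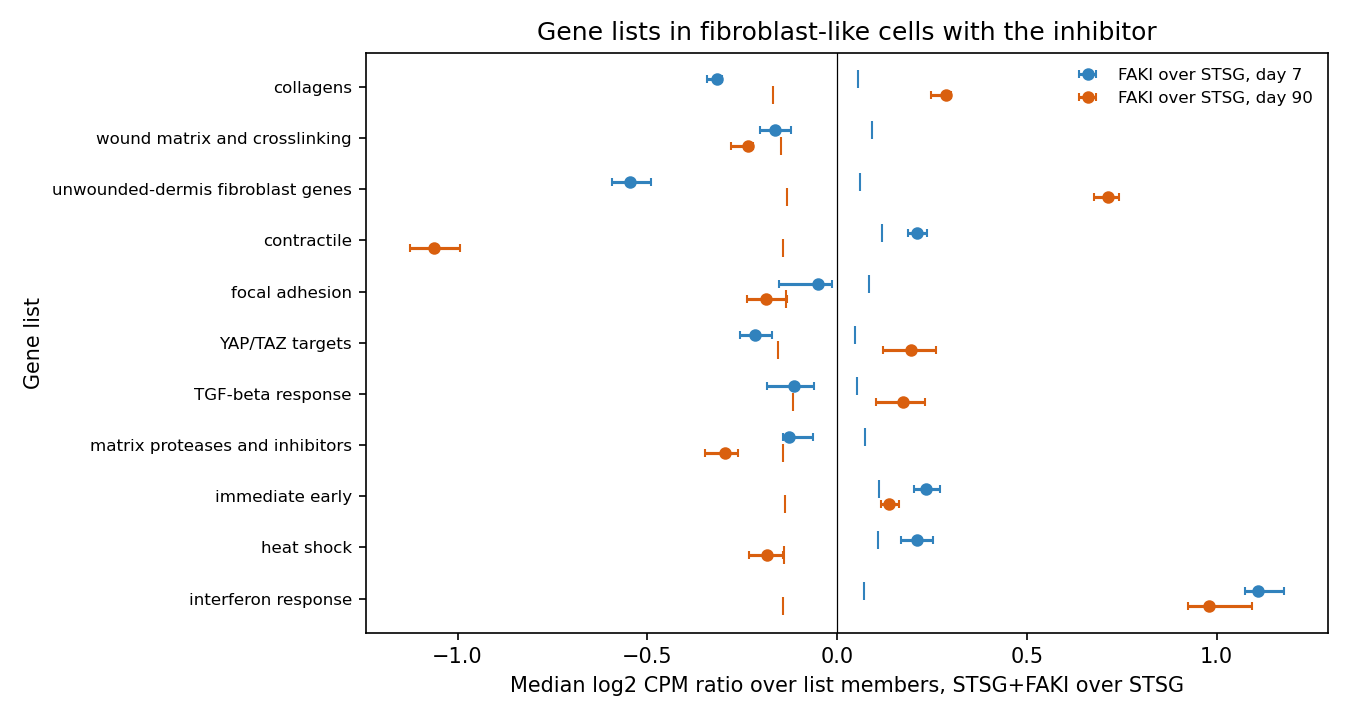
Median log2 CPM ratio (horizontal axis) of each gene list in fibroblast-like cells, inhibitor over untreated graft at each day, with 95% counting intervals and a tick at the median of the random lists. Contractile genes lie at 0.21 at day 7 and -1.06 at day 90.

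At day 7 the rise of interferon response genes was then followed through the other classes. It was present in each class compared, with medians of 1.42 in pericyte or smooth muscle-like cells (13 of 14 genes higher), 0.84 in endothelial-like cells (15 of 19), 1.01 in keratinocyte-like cells (18 of 20), 1.38 in T or NK-like cells (14 of 16), 1.92 in mast-like cells (8 of 9 higher, 1 lower) and 1.78 in cluster 14 (18 of 18). CXCL10 reached 8094 against 326.9 CPM in pericyte or smooth muscle-like cells (24.8-fold), 6289 against 462.2 in endothelial-like cells (13.6-fold) and 2661 against 514.8 in keratinocyte-like cells (5.17-fold). It is a leading gene of pericyte-like cluster 0. In T or NK-like cells CXCL10 was 5.80-fold higher and in mast-like cells 11.5-fold, on 87 against 10 UMIs, and in those classes free RNA was not excluded. Intracellular response genes rose in T or NK-like cells as well, MX1 3.70-fold and IFI6 3.35-fold.

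**Figure D3:**
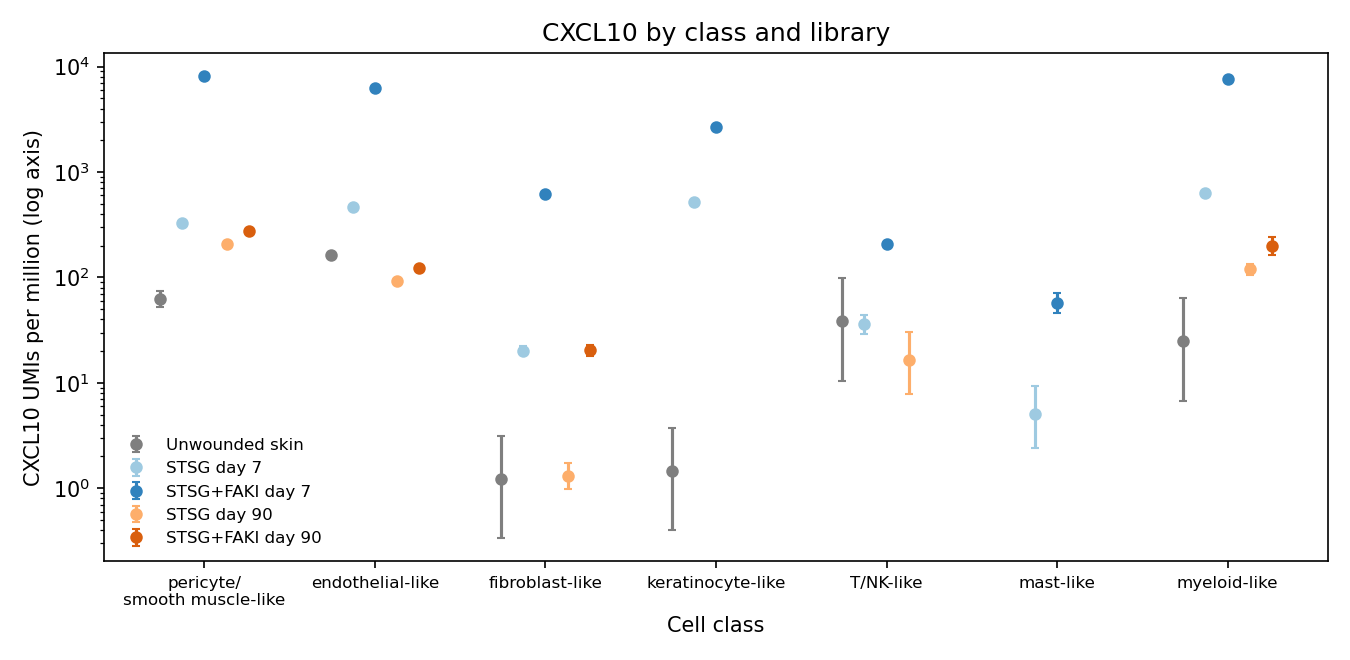
CXCL10 in CPM (log axis) per cell class and library, with exact 95% Poisson intervals, where groups with 0 UMIs are not drawn and classes under 20 cells in a library are missing. At day 7 the treated graft stands above the untreated one in each class compared, with 8094 against 326.9 CPM in pericyte or smooth muscle-like cells.

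Antigen presentation genes were also above the random lists at day 7, at 1.80 in pericyte or smooth muscle-like, 0.38 in endothelial-like, 0.84 in keratinocyte-like, 0.47 in T or NK-like and 1.71 in mast-like cells and 0.39 in cluster 14. At most 9 of the 15 genes on that list could be read in any class. Collagens were below them at -1.08 in endothelial-like (8 of 10 lower), -1.23 in myeloid-like (2 of 3 lower), -0.83 in T or NK-like and -0.64 in mast-like cells, inside them at 0.17 in keratinocyte-like cells (3 of 8 higher, 1 lower), and above them at 1.39 in cluster 14 (6 of 6 higher). The direction in myeloid-like cells did not hold, as COL1A1, COL1A2 and COL3A1 turned to 1.15, 0.93 and 0.94 with the looser filter and to 0.45, 0.62 and 1.24 with cluster 14 counted in. Contractile genes lay at -0.53 in endothelial-like (5 of 11 lower) and -0.24 in T or NK-like cells (1 of 8 lower), below the random lists. They lay above them at 0.17 in pericyte or smooth muscle-like (0 of 14 changed), 0.63 in keratinocyte-like (4 of 7 higher) and 2.20 in cluster 14 (6 of 9 higher). Free RNA of other classes was not excluded for either list. A shift between the endothelial-like clusters was not excluded either. Cluster 17, with the collagen COL15A1 among its leading genes, held 139 of 1443 untreated and 49 of 1159 treated cells of that class. In keratinocyte-like cells chemokines and inflammatory cytokines lay at 0.51 (6 of 12 higher, 0 lower), differentiated keratinocyte genes lay at -0.51 (2 of 5 lower, 3 in between), and wound keratinocyte genes at 0.29 (1 of 5 lower, 4 in between), inside the random lists. The wound keratinocyte list lacked KRT6A, KRT16 and KRT17, as 6 of its 14 genes had a matching symbol. In endothelial-like cells angiogenic genes lay at -0.18 (1 of 11 higher, 10 in between), but at 0.05 with the mean of per-cell CPM, and endothelial activation genes lay at -0.04 with 0 of 7 changed. Chemokines there lay at -0.25 (1 of 13 higher, 1 lower). Immediate early genes lay at -0.24 in pericyte or smooth muscle-like cells (4 of 12 lower, percentile 0.72) and at 1.02 in cluster 14 (8 of 11 higher), and between 0.05 and 0.17 in keratinocyte-like, T or NK-like and mast-like cells. Cluster 14 cells had a median of 4800 UMIs in the treated and 8137.5 in the untreated graft. Free RNA was not excluded for its immediate early genes either. Heat shock genes lay at 0.19 in endothelial-like cells (1 of 10 higher) and cell cycle genes at 0.48 in keratinocyte-like cells (1 of 4 higher), at -0.31 in T or NK-like cells (1 of 3 lower) and at -0.01 in pericyte or smooth muscle-like cells.

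The same treatment question was asked of fibroblast-like cells at day 90, with 2099 untreated and 789 treated cells. Contractile genes were lower with the inhibitor, genes of unwounded dermal fibroblasts were higher, and collagens were slightly higher. The median log2 ratio of all genes at 50 CPM in both libraries was -0.13, and random lists lay near it, so lists are read against that level. The contractile list lay at -1.06 (-1.13 to -0.99), with 9 of 10 genes lower and 0 higher. The tropomyosin TPM2 was 2.77-fold lower (221.0 against 611.1 CPM), the myosin light chain MYL9 2.65-fold and ACTA2 2.63-fold (213.5 against 562.0 CPM), while the filamin FLNA was in between at 0.783. The unwounded-dermis list lay at 0.71, above all random lists, with 8 of 15 higher, 1 lower and 6 in between. CLEC3B (tetranectin) rose 4.08-fold (1015 against 248.8 CPM), the stem cell antigen CD34 3.58-fold and TNXB 3.05-fold, whereas the Wnt modulator SFRP2 was 2.40-fold lower. Although SFRP2 is on this list, it stood far above unwounded skin in both grafts at day 90. Its lower value in the treated graft thus lay nearer the unwounded level. Collagens lay at 0.29, percentile 99.8, with 1 of 14 higher (COL6A3, 1.61-fold), 0 lower and 13 in between, such as COL1A1 (log2 ratio 0.33) and COL3A1 (0.37).

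At day 90 the fibroblast-like class was also spread differently over its clusters in the untreated and the treated graft. Cluster 10, led by THBS4, SFRP2, COL11A1 and TNMD, took 44.8% of untreated and 18.1% of treated fibroblast-like cells, cluster 15, led by CPZ, CCDC80, TNXB and PI16, took 14.0% and 47.4%, and cluster 9 took 16.2% and 0.761%. With the 3 shared clusters (7, 10 and 15) weighing the same, the medians shrank to -0.32 for contractile genes, 0.18 for unwounded-dermis genes and 0.074 for collagens. In that setting TPM2 had a log2 ratio of -0.34 in place of -1.47, MYL9 -0.49 in place of -1.40, ACTA2 -0.54 in place of -1.40, CLEC3B 0.36 in place of 2.03, CD34 0.47 in place of 1.84 and TNXB 0.18 in place of 1.61. SFRP2, a leading gene of cluster 10, stayed at -1.21 against -1.26. ACTA2 lay at -0.75 with doublets kept.

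In fibroblast-like cells at day 90, YAP/TAZ targets lay at 0.20 (3 of 11 higher, 0 lower, percentile 99.2), with CCDC80 (2.13-fold) and the coagulation factor gene F3 (1.93-fold) higher. Interferon response genes lay at 0.98 with 3 of 3 higher, IFI6 at 2.61-fold, ISG15 at 1.97-fold and IRF1 at 1.95-fold. CXCL10, below the 50 CPM asked of list members, had a log2 ratio of 3.95, but 1.02 with doublets kept. Chemokines and inflammatory cytokines lay at 0.19 (4 of 10 higher, 2 lower), with CXCL12 2.66-fold and the macrophage growth factor CSF1 2.55-fold higher and CXCL14 lower at a ratio of 0.405. Immediate early genes lay at 0.14 (3 of 12 higher, among them MYC 1.96-fold and ZFP36 1.80-fold, percentile 98.5), with EGR1 at 1.07. Wound matrix and crosslinking genes lay at -0.24 inside the random lists (1 of 19 higher, POSTN at 1.54-fold, and 4 lower), with the cartilage matrix gene COMP 9.90-fold and the lysyl hydroxylase PLOD2 2.60-fold lower. Matrix proteases and inhibitors lay at -0.29 (2 of 10 lower), but at 0.12 in the shared clusters. Focal adhesion genes lay at -0.19 (2 of 14 lower, the integrin genes ITGB1 and ITGA5), TGF-beta response genes at 0.17 (1 of 7 higher and 1 lower), heat shock genes at -0.19 (0 of 10 changed), hypoxia and glycolysis genes at -0.21 (1 of 6 lower) and the PI3K-AKT list at 0.35 (1 of 2 higher). The cell cycle list held 1 gene, lower at -0.96, but at 0.55 in the shared clusters. PTK2 had 23.5 against 23.2 CPM (ratio 1.01, 0.891 to 1.15). With the shared clusters weighing the same, CCDC80 (log2 ratio 0.22), IFI6 (0.50), CSF1 (0.58), CXCL14 (-0.53), ZFP36 (0.577), POSTN (0.12) and ITGB1 (-0.21) no longer reached 1.5-fold, and ITGA5 turned to 0.036.

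Of the 20 genes with the largest ratios at day 90, the lowest were leading genes of cluster 9, which the treated graft nearly lacked. The collagenase MMP13 had 1 UMI against 9622 (ratio 0.000291, 7.36e-06 to 0.00162), HPS5 was 118-fold lower (8.69 against 1024 CPM), MMP3 86.3-fold and IL11 31.6-fold. In the shared clusters the log2 ratio was -3.87 for MMP13, -1.63 for HPS5, -1.35 for MMP3 and -1.37 for IL11. TNMD (tenomodulin), a leading gene of cluster 10, was 3.50-fold lower (71.2 against 248.9 CPM). Of the 10 lowest genes, 7 were still lower by 1.5-fold in the shared clusters, and 4 of the 10 highest were still higher. Those 4 were PLXDC1, a leading gene of cluster 15 (3.30-fold over all cells), the lipid carriers APOE (2313 against 742.0 CPM, 3.12-fold) and APOD (2.53-fold), and CXCL12. KERA (keratocan, 2.34-fold higher over all cells) and CLU (clusterin, ratio 0.374) turned to -0.066 and 0.063 on the log2 scale. With each library clustered alone, APOD reached 3.61 on the log2 scale and CXCL12 2.63.

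In other classes at day 90 the interferon response list lay at 0.29 in pericyte or smooth muscle-like cells (3 of 10 higher) and 0.24 in endothelial-like cells (3 of 16 higher), both above the random lists. In mast-like cells it lay at -0.16 (1 of 7 higher, 2 lower). Collagens were below the random lists, unlike in fibroblast-like cells, at -0.42 in pericyte or smooth muscle-like (3 of 12 lower), -0.43 in endothelial-like (2 of 10 lower) and -1.22 in mast-like cells (3 of 3 lower), as were contractile genes at -0.36 in endothelial-like cells (0 of 10 changed). Free RNA of other classes was not excluded there. Immediate early genes lay at 0.18 in pericyte or smooth muscle-like cells with 0 of 13 changed, and heat shock genes at -0.22 in endothelial-like cells with 0 of 10 changed and at -0.36 in mast-like cells (2 of 10 lower). Angiogenic endothelial genes lay at -0.11 and endothelial activation genes at -0.17, each with 0 changed. PTK2 had ratios of 1.04 in pericyte or smooth muscle-like and 0.981 in endothelial-like cells, after 0.896 and 0.750 at day 7.

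For myeloid-like cells at day 7, 299 untreated and 140 treated cells were compared, all of cluster 16. Interferon response genes rose, with a median of 0.71 (0.57 to 0.90) and 8 of 16 genes higher and 0 lower. The median reached 1.54 with each library clustered alone and 1.46 with cluster 14 counted in. CXCL10 rose from 631.9 to 7609 CPM, ISG20, an RNA exonuclease, 4.97-fold, IRF1 3.29-fold and the immune checkpoint ligand CD274 4.62-fold. With cluster 14 counted in, the log2 ratio of CXCL10 went from 3.59 to 4.37 and that of ISG20 from 2.31 to 3.15. CD274 ranged from 1.51 at Leiden resolution 2 to 2.92 with each library clustered alone. Chemokines and inflammatory cytokines lay at 0.17 (8 of 20 higher, 0 lower), with the monocyte attractant CCL8, a leading gene of the class's cluster, at 8971 against 3087 CPM. S100A8 and S100A12 were 10.4-fold and 8.66-fold higher, and both are leading genes of cluster 14, so free RNA remained possible. From log2 ratios of 3.38 and 3.11 they moved to 1.89 and 1.65 with the looser filter and to 2.07 and 1.99 with each library clustered alone. Tissue-macrophage genes lay at -0.40 (3 of 10 lower, 7 in between), with FOLR2 at a ratio of 0.333 and the complement gene C1QB at 0.607. Lipid-handling macrophage genes lay at 0.01 (1 of 9 lower), but at -0.74 with cluster 14 counted in, and antigen presentation genes at 0.07 (3 of 8 higher), with TAP1 at 2.64-fold. Further genes of the 20 with the largest ratios were the membrane gene MS4A7 (3.83-fold) and HPS5 (8.91-fold, uncertain as above, and 1.80 on the log2 scale with the looser filter), and, lower, the complement gene C3 (ratio 0.340), the chemokine CCL14 (0.385), the lectin CD209 (0.389) and the splicing factors SRSF5 (0.408), SRSF6 (0.480) and SRSF3 (0.497). PTK2 rested on 12 against 16 UMIs, too few to show a difference.

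At day 90 only 50 treated myeloid-like cells stood against 261 untreated ones, and many gene ratios turned with the assignment of cells. Chemokines and inflammatory cytokines lay at 0.43 (4 of 14 higher, 1 lower), and at 0.12 with each library clustered alone. CCL2, which attracts monocytes, rose 2.26-fold (8237 against 3649 CPM), and the transcription factor ETV3 2.17-fold. The lipase LPL had 66 against 5 UMIs (60.0-fold, 24.4 to 191; 3.11 on the log2 scale in place of 5.91 with each library clustered alone). Lower were the gelatinase MMP9 (6.20-fold), the cytokine IL10 (4.84-fold, -0.91 in place of -2.28 on the log2 scale with doublets kept), APOE (ratio 0.342) and MS4A7 (0.392). Lipid-handling genes lay at -0.27 (2 of 10 higher, 2 lower), tissue-macrophage genes at 0.17 (1 of 11 lower), antigen presentation genes at 0.08 (0 of 8 changed), interferon response genes at 0.12 (3 of 14 higher, 1 lower) and heat shock genes at 0.11. Immediate early genes lay at -0.29 but at 0.63 with each library clustered alone. In that setting CXCL10 (1.68-fold), SPP1 (1.52-fold) and CCR7 (7.07-fold) turned to -0.15, -1.11 and -0.21.

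Against unwounded skin, with its 265 fibroblast-like cells, each graft had higher medians of contractile and wound matrix genes. The compared cells lay largely in different clusters. Clusters 7 and 15 held 44.9% and 46.0% of the class in unwounded skin and cluster 10 held 0 cells, while cluster 5 held 50% and 44.5% of the untreated and treated class at day 7. The median of all genes was shifted by 0.27 and 0.33 in the untreated and treated graft at day 7 and by 0.16 and 0.05 at day 90, and list medians are read beside those shifts. Contractile genes lay at 2.44 and 3.14 at day 7 and at 2.83 and 1.77 at day 90, with 9 of 9, 8 of 9, 10 of 10 and 7 of 8 higher. With the mean of per-cell CPM these became 1.80, 2.12, 2.22 and 1.16. ACTA2 was 18.1-fold and 28.9-fold higher in the untreated grafts at day 7 and day 90. The actin-binding gene TAGLN was 31.9-fold higher in the untreated and 14.3-fold higher in the treated graft at day 90. Unwounded-dermis genes lay at -1.71 and -2.73 at day 7 and at -1.45 and -0.40 at day 90, with 12 of 17, 11 of 17, 11 of 16 and 7 of 16 lower. Wound matrix genes lay at 0.60, 0.65, 1.19 and 0.39 in the order untreated and treated at day 7 and untreated and treated at day 90, with TNC (tenascin C) at 19.1-fold, 24.3-fold, 25.3-fold and 17.2-fold. Collagens lay at -0.35, -0.83, -0.33 and 0.01 in that order. COL1A1 was 3.53-fold lower in the untreated graft at day 7, while COL11A1, a fibrillar collagen of cartilage and a leading gene of cluster 10, was 53.8-fold higher in the untreated and 36.3-fold higher in the treated graft at day 90.

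Chemokines and inflammatory cytokines in fibroblast-like cells lay at 1.45 and 2.20 over unwounded skin at day 7 and at -0.18 and 0.09 at day 90. Immediate early genes were below unwounded skin in each graft, at -1.50, -1.48, -0.74 and -0.58, and those genes are also raised by digestion. The interferon response list lay at 1.27 in the treated graft at day 7 (9 of 10 higher) and at 0.17 in the untreated one, where median-ratio scaling gave -0.10. The serine protease PRSS35 was 129-fold higher in the untreated graft at day 7, on 6 UMIs in unwounded skin, 192-fold in the treated one, and 220-fold and 82.9-fold at day 90. SFRP2, although on the unwounded-dermis list, was 39.9-fold higher in the untreated graft at day 7 and 139-fold and 58.0-fold at day 90. MMP13 had 0 UMIs in unwounded fibroblast-like cells and was at least 263-fold higher in the untreated graft at day 90, as COMP was at least 96.8-fold. PRSS35 and MMP13 are leading genes of cluster 9, and SFRP2 of cluster 10. The keratin KRT8 and the secreted protein MYOC were among the 5 lowest genes in each graft, and CLEC3B was 16.5-fold lower in the untreated graft at day 7. KRT8 is on the marker list of skin gland epithelium, the best class of unnamed cluster 29. That cluster held 38 unwounded cells, 0 in either graft at day 7, and 22 and 24 at day 90. Its RNA was not screened for, so free RNA remained possible for KRT8.

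In keratinocyte-like cells at day 7 the interferon response list lay at 4.25 in the untreated and 5.66 in the treated graft over unwounded skin (11 of 12 and 20 of 20 higher). Members needed 50 CPM in only 1 of the 2 libraries, so genes low in the 137 unwounded cells could enter through the graft alone. That favours a count of higher genes, and the medians rest on different numbers of members. Wound keratinocyte genes lay at 1.54 and 1.89 (5 of 5 and 4 of 4 higher) and differentiated keratinocyte genes at -1.44 and -2.29 (6 of 7 and 7 of 7 lower). Only 6 of the 14 wound keratinocyte genes had a matching symbol, so the keratins KRT6A, KRT16 and KRT17 were not read. Cell cycle genes in pericyte or smooth muscle-like cells lay at 2.90 and 3.79, and at 1.57 and 1.61 with the mean of per-cell CPM. In endothelial-like cells they lay at 2.08 and 2.02 but at -0.46 and -0.52 with that mean. Angiogenic endothelial genes lay at 0.55 in the untreated (4 of 11 higher) and 0.23 in the treated graft.

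At day 90 against day 7, the fibroblast-like class held more collagen RNA in both grafts and less interferon response and chemokine RNA. Its cells lay largely in other clusters on the later day, so a change within cells and a change in which cells were present were not told apart. In the untreated grafts cluster 5 went from 50% to 3.86% of the class and cluster 10 from 0.639% to 44.8%, and in the treated grafts cluster 5 went from 44.5% to 2.15%, cluster 9 from 33.3% to 0.761% and cluster 15 from 0.916% to 47.4%. The median of all genes shifted by -0.17 in the untreated and -0.35 in the treated grafts. Collagens lay at 0.69 (8 of 14 higher, 3 lower) and 1.07 (9 of 14 higher), with COL1A1 up 2.65-fold and 4.11-fold. Unwounded-dermis genes lay at 0.50 (7 of 15 higher, 4 lower) and 2.03 (10 of 16 higher, 2 lower), with PI16, a leading gene of cluster 15, up 14.1-fold and CLEC3B up 10.8-fold in the treated grafts. Contractile genes lay at 0.35 in the untreated grafts (4 of 10 higher) and at -0.67 in the treated ones (6 of 9 lower). Interferon response genes lay at -1.56 (5 of 6 lower) and -1.81 (10 of 10 lower), and chemokines and inflammatory cytokines at -1.11 (11 of 12 lower) and -1.47 (12 of 15 lower). Immediate early genes lay at 0.89 (8 of 12 higher, 0 lower, 4 in between) and 0.86 (8 of 12 higher, 1 lower, 3 in between). In the untreated grafts TNMD rose 87.9-fold and the matrix glycoprotein THBS4 8.88-fold, both leading genes of cluster 10, while the retinoic acid hydroxylase CYP26B1 had a ratio of 0.0653 and the BMP antagonist GREM1, a leading gene of cluster 5, 0.161. In the treated grafts HPS5 fell to a ratio of 0.00353, IL11 to 0.00982 and SERPINE2 to 0.0659, all leading genes of cluster 9. Day and animal could not be separated, since each day is another library.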

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

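The tests of a shift between the fibroblast-like clusters, of reads from a neighbouring gene, and of the animal or graft site were chosen only after the result was seen. The results below stood out because the ratio of treated over untreated graft lay in opposite directions at day 7 and day 90. Each compares 1 library pair per day, and the difference between days was not tested. In fibroblast-like cells the log2 value at day 90 minus that at day 7 was 0.60 for collagens (-0.32 at day 7, 0.29 at day 90), 1.26 for unwounded-dermis genes (-0.55, 0.71) and 0.41 for YAP/TAZ targets (-0.22, 0.20). It was 0.42 for immediate early genes in pericyte or smooth muscle-like cells (-0.24, 0.18) and -0.41 for heat shock genes in endothelial-like cells (0.19, -0.22), both lists that digestion also raises.

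Of single genes in fibroblast-like cells, TNXB rose relative to the untreated graft between days by 2.90, CXCL12 by 2.43, CCDC80 by 2.01 and POSTN by 1.38. With the shared fibroblast-like clusters weighing the same, the day 90 values fell to 0.18 for TNXB, 0.86 for CXCL12, 0.22 for CCDC80 and 0.12 for POSTN, and the medians above to 0.074 for collagens and 0.18 for unwounded-dermis genes. HPS5 had a difference of -9.92, IL11 of -7.61 and ODAPH of -2.78. These 3 are leading genes of cluster 9, which held 33.3% of treated fibroblast-like cells at day 7 and 0.761% at day 90. In myeloid-like cells MS4A7 had a difference of -3.29 (1.94 at day 7, -1.35 at day 90), on 50 treated cells at day 90.

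The first pattern weighed was the rise of interferon response genes in each compared class at day 7. Free RNA from 1 source would give CXCL9 and CXCL10 the same ratio in each class. The ratio differed 18.6-fold between endothelial-like (0.504) and myeloid-like cells (0.0271), with separate intervals. That argues against a single source of these chemokines for the classes as a whole. Free RNA from several classes could also give unequal ratios. The ratios are those of the treated graft and not of its excess over the untreated one. Other list members were not tested in this way. In T or NK-like and mast-like cells the ratios (0.149 and 0.195) overlapped that of cluster 14 (0.159), so CXCL10 there may be free RNA. The median was at least 1.5-fold higher in 15 of 16 clusters, but those that made up a whole class or belonged to none cannot test a shift between clusters inside a class. In pericyte or smooth muscle-like (4 of 4), T or NK-like (3 of 3) and fibroblast-like clusters (2 of 3) such a shift is argued against, the exception being fibroblast-like cluster 9 at 0.28. Of the endothelial-like clusters only 1 was tested (0.99), and in the other classes a shift stays untested. The animal or graft site of a library cannot be told apart from treatment with 1 library per group, so an effect of the inhibitor stays open and untested.

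The second pattern was the lower contractile RNA of fibroblast-like cells at day 90. RNA of smooth muscle cells in the untreated graft would lift smooth muscle markers as much as contractile genes, but contractile members stood at a median of 20.6% of the pericyte or smooth muscle-like level and marker genes at 0.549%, a ratio of 37.4. That argues against it for the median, although ACTG2 and MYLK stood at only 0.491% and 2.77%. A shift between clusters may account for a large part, since relative to all genes the median was -0.32 in cluster 7, -0.22 in cluster 15 and -0.05 in cluster 10, against -0.93 over the class with median-ratio scaling. Because the clusters were made from the same genes, a change within cells and a change in which cells were present cannot be told apart, and an effect of the inhibitor or of the animal stays open.

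The third pattern was the level of HPS5 and CPSF6 far above that in other classes. CPSF6 stood 60.2-fold higher in myeloid-like than in fibroblast-like cells of the untreated graft at day 7. The 5 other measured genes of the cleavage and polyadenylation machinery (CPSF2, CPSF3, CPSF4, CPSF7 and NUDT21) lay between 0.420 and 1.01. HPS5 stood 99.7-fold higher in fibroblast-like than in pericyte or smooth muscle-like cells of the treated graft at day 7, and its partner HPS3 1.61-fold. In a gene table of assembly Sscrofa11.1 CPSF6 lies beside LYZ, which had 1 UMI in myeloid-like cells, and HPS5 near SAA2 and SAA4, so reads of a neighbouring gene may be counted under these names. Without the reads and the annotation used for counting this could not be decided, and no biological explanation was tested.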

How the results depend on the processing

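All tests with cluster 14 counted as myeloid-like and with the shared fibroblast-like clusters weighing the same were chosen only after the result was seen. For 632 results, 7210 values were computed under 14 alternative settings. Of these, 5096 stayed within the counting interval of the reported value, 2053 moved outside it and 61 changed sign. Only values past the 1.5-fold rule, lists outside the random lists and share ratios with an interval off 1 could count as changing sign, and other changes of sign are among those that stayed or moved. The intervals cover counting error only and are narrow, so a value outside them often differs little. Myeloid-like cells at day 90 rested on 50 treated cells, and many changes of sign fell there. No paired analysis was possible because the labels do not say which libraries share an animal. Values below are log2 medians or ratios of inhibitor over untreated graft unless they are called a share ratio or another comparison is named. The cause was not tested except where the setting gives it by construction.

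With the looser filter (200 genes, 40% mitochondrial UMIs) the endothelial-like interferon response at day 7 was 0.77. In myeloid-like cells COL1A2 and COL1A1 turned to 0.93 and 1.15 at day 7, and FN1 and TAGLN to 0.11 and 0.21 at day 90. With the stricter filter (1000 genes, 10%) the day 7 share ratios were 0.71 for myeloid-like and 1.36 for T or NK-like cells, and that of fibroblast-like cells turned from 0.881 to 1.05. The interferon response at day 7 was 1.28 in fibroblast-like and 1.32 in myeloid-like cells, and COL1A1 there turned to 0.21. At day 90 myeloid-like immediate early genes turned from -0.29 to 0.44, GADD45A to 0.49, CXCL10 to -0.73 and SPP1 to -0.66. The myeloid-like interferon response of untreated grafts from day 7 to day 90 turned from -0.37 to 0.071.

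With doublets kept the interferon response at day 7 was 1.27 in fibroblast-like, 1.23 in myeloid-like and 0.80 in endothelial-like cells, and contractile genes at day 90 were -0.84. In myeloid-like cells COL1A2, COL1A1, TAGLN and ACTA2 turned to 0.57, 0.44, -0.57 and -1.02 at day 7, and immediate early genes, CXCL10 and ACTA2 to 0.18, -0.024 and 0.83 at day 90. At Leiden resolution 0.5 the myeloid-like share ratio at day 7 was 0.79 and the interferon response 1.46, COL1A2 and COL1A1 turned to 0.58 and 0.42, and at day 90 immediate early genes, GADD45A, CXCL10 and SPP1 to 0.25, 0.69, -0.31 and -0.56. The change of the interferon response between days turned to 0.079. At resolution 2 the share ratio was 0.53, and immediate early genes and GADD45A turned to 0.32 and 0.22 at day 90.

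With each library clustered alone the fibroblast-like share ratio at day 90 was 0.61, unwounded-dermis genes 1.05 and contractile genes -1.23. The myeloid-like share ratio at day 7 was 0.84 with an interferon response of 1.54. At day 90 myeloid-like chemokines were 0.12, and immediate early genes, CCR7, GADD45A, CXCL10, IFIT1, SPP1 and ACTA2 turned to 0.63, -0.21, 1.09, -0.15, 0.74, -1.11 and 0.044. With each cell assigned by its own markers the share ratios at day 7 were 0.695 for myeloid-like and 2.0 for T or NK-like cells, and the interferon response was 1.21, 1.32 and 0.74 in fibroblast-like, myeloid-like and endothelial-like cells. Myeloid-like chemokines at day 90 were 0.52, and immediate early genes, GADD45A, CXCL10 and SPP1 turned to 0.34, 0.54, -0.19 and -0.64.

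Median-ratio scaling moved the fibroblast-like medians by the shift of all genes, by construction. Collagens were -0.38 at day 7 and 0.42 at day 90, unwounded-dermis genes 0.84 and contractile genes -0.93 at day 90, and unwounded-dermis genes 2.38 between days in treated grafts. Without the 50 most abundant genes collagens were -0.36 and 0.37, and unwounded-dermis genes 0.79 at day 90 and 2.31 between days in treated grafts. Neither scaling turned a called value. With the mean of per-cell CPM collagens were -0.27 at day 7, the endothelial-like interferon response 0.98, unwounded-dermis genes 0.49 at day 90, and contractile genes 2.22 in the untreated graft at day 90 over unwounded skin. Endothelial-like angiogenic genes turned to 0.050 at day 7. Endothelial-like cell cycle genes turned to -0.46 and -0.52 in the untreated and treated graft at day 7 over unwounded skin, and to 0.27 and 0.31 from day 7 to day 90.

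With list members at 10 CPM the fibroblast-like interferon response at day 7 was 1.36, contractile genes 2.60 in the untreated graft at day 90 over unwounded skin, and proteases turned to 0.26 at day 7. At 1 UMI these were 1.58, 2.5 and 0.26, contractile genes at day 90 -1.14 and the myeloid-like interferon response 0.57, while hypoxia genes turned to -0.016 at day 7 and proteases to -0.073 from day 7 to day 90 in untreated grafts. With the shared fibroblast-like clusters weighing the same, which removes differences in cluster sizes by construction, collagens were -0.30 and the interferon response 1.45 at day 7, and collagens 0.074, unwounded-dermis genes 0.18 and contractile genes -0.32 at day 90. There proteases, KERA, CLU, ITGA5, TGFBI, IL6 and UBE2C turned to 0.12, -0.066, 0.063, 0.036, 0.12, 0.071 and 0.55. With cluster 14 counted as myeloid-like the share ratio at day 7 was 0.793 and the interferon response 1.46, COL1A2 and COL1A1 turned to 0.62 and 0.45 at day 7, immediate early genes, GADD45A, CXCL10 and SPP1 to 0.23, 0.57, -0.29 and -0.55 at day 90, and the interferon response between days to 0.079.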

Other observations

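All genes and clusters of this part were chosen after their values were seen, and no explanation was tested for them. In T or NK-like cells at day 7 the cytokine IL17F stood at 456.7 CPM with the inhibitor and 27.35 CPM without (16.7-fold, 13.2 to 21.4), and IL17A was 8.50-fold higher. Both are leading genes of T or NK-like cluster 18, which held 388 of 1897 treated and 246 of 960 untreated cells of the class, a smaller part in the treated graft. In mast-like cells CSF2, a growth factor of myeloid cells, stood at 31.2 against 341.6 CPM, a ratio of 0.0912. In keratinocyte-like cells KRT15, a keratin of basal and hair follicle cells, stood at 133.9 against 776.1 CPM, 5.79-fold lower.

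The unnamed cluster 20, led by CCR7, BCL2A1 and CD83 and carrying markers of 2 classes, held 147 untreated and 150 treated cells at day 7. Its interferon response median was 2.14, with 14 of 15 genes higher with the inhibitor. Only fibroblast-like clusters 5, 7 and 9 held at least 100 cells in both libraries at day 7. Among these 3 the interferon response was highest in cluster 7 at 2.53, with 18 of 18 genes higher. The medians of clusters 5 and 9 rested on fewer genes, 12 and 6. Cluster 31 held 49 cells, of which 48 came from the treated graft at day 7, and carried endothelial and pericyte markers together. Cluster 25, also unnamed, held 173 untreated and 76 treated cells at day 7 and 3 of each at day 90.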
